A study of Mus musculus with 6 samples.

How the data were processed

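The samples were abdominal aortas of male ApoE-/- mice on the C57BL/6J background, a strain that lacks apolipoprotein E and is prone to atherosclerosis and aneurysm. The labels name 3 libraries from mice with an abdominal aortic aneurysm (AAA) induced by angiotensin II and 3 libraries from control mice. Each library was made by methylated RNA immunoprecipitation, in which an antibody against N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, pulls down RNA fragments that are then sequenced. Per the labels' protocols, total RNA was cleared of ribosomal RNA, the immunoprecipitation used the GenSeq m6A-MeRIP kit, and the library was built from the immunoprecipitated RNA. The treatment of the control mice and the dose and duration of angiotensin II are not given in the sources used here.

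The authors deposited 1 peak list per library. Whether the peaks of each list were called and bounded from that library alone is not stated. Per the submitters' processing notes, the tools were cutadapt 1.9.3, HISAT2 2.0.4 and Cuffdiff, and the genome build was GRCm38 (mm10). The peak names in the deposited lists are those of the MACS peak caller, whose version and settings, and whether an input library served as background, are not given in the sources used here. Each line of the deposited lists has 6 columns, with the position, the peak name, the strand and a score, which is the authors' value from the peak caller for that peak. The deposited scores ran from 50 to 3233, with 13.1% of the peaks of AAA libraries and 5.30% of those of control libraries at 3100 or more, where the scores pile up (the cap below). The scale of the score is not stated, so scores served to rank and filter peaks within a list, to order genes and regions by their mean or lowest score over libraries, and to look for duplicated libraries, and no difference in score between groups was tested.

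Start positions in the lists are counted from 0, since 5.35% of starts plus 1 equal the start of a gene in the annotation and 0.278% of starts do. Coordinates below are counted from 1. The peak names carry running numbers that increase along each chromosome without overlap between chromosomes. The highest number reached 77821 in AAA libraries and 164840 in control libraries while the longest list had 12388 peaks, so each list is a part of what was called. The lists hold no read counts, so the depth of the libraries is unknown and no counting interval could be given.

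Only a table of gene coordinates of the same build, without exons, strands or sequence, was used as annotation. A peak was therefore assigned to the gene whose body it overlapped by at least 1 base, with protein-coding genes preferred. Where several genes overlapped, the strand of their unambiguous peaks decided. Of 27855 different intervals, 1260 overlapped several candidate genes, 339 of these were resolved by strand, and 1031 intervals (3.70%) stayed without a gene. The plan had been to use gene names in the files or overlap with exons, neither of which was at hand, so overlap with the gene body, planned as the alternative, became the main assignment. Introns, exons and UTRs could not be told apart. Position was given as the share of peaks whose midpoint fell in the first or last 10% of the gene body in the direction of the peak strand, introns included. The planned search for the m6A sequence motif was not run, since it needs the genome sequence.

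Peaks of the 6 libraries were merged into regions where they shared at least 1 base on the same strand. A region or gene was counted in a library when at least 1 peak of that library lay in it. Similarity of lists was the Jaccard index, the shared bases divided by the bases in either list, for all 15 pairs of libraries. Values per library were compared by an exact two-sided permutation test over the 20 arrangements of the 6 libraries, whose smallest p is 0.1. No single region or gene can pass a threshold of 0.05 with 3 libraries against 3, so the text counts those with a peak in all 3 libraries of one group and none of the other.

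Gene lists with 796 genes in all were fixed before the data were examined, as was the rule for naming genes, and all 796 symbols matched the annotation. Of the 25 lists, 23 with at least 5 genes carrying a peak were tested with a two-sided Fisher exact test of list members against the other genes with a peak in any library, separately for genes found only in AAA and only in control. The 46 p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes are not independent replicates, so these tests describe the 6 libraries. The naming rule took all genes of the m6A writers, erasers and readers list with a peak, up to 4 members of each other list found in all 3 libraries of one group only, the 8 such genes outside the lists in each direction, and the 5 leading genes found in all 6 libraries. Genes were ranked by the mean over libraries of their highest peak score, with ties by symbol. Ties at the score cap were many: 38 AAA-only genes outside the lists and 123 genes in all 6 libraries had a mean of at least 3100. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule selects are not reported here.

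The alternatives tried were leaving out each library in turn, the better-scoring 50% of each list, equal list lengths (the top 4128 peaks of each library, the length of the shortest list), a reciprocal overlap of at least 50%, ignoring strand, a looser criterion of at least 2 more libraries of one group, a background of genes in at least 2 libraries, position weighted by bases, replicate number as a block and, added after seeing the data, unambiguous peaks only. The counting of regions was run on simulated libraries with 16148 regions, where 100% of 200 planted group-specific regions were recovered. The planted peaks always overlapped between libraries, so this recovery was fixed in advance and checks the code only. The simulated libraries did not differ in list length between groups as the real ones do. The list test was run on 8000 simulated genes, where 5 of 5 planted lists of 30 genes, 80% of them group-specific, and 0 of 15 others were called. Smaller lists or weaker shifts, as in most of the real lists, were not simulated. No 2 libraries were duplicates: at most 1 peak per pair with the same coordinates also had the same score under the cap. Identical coordinates were frequent, in 5900 to 6364 peaks per pair of AAA libraries. Per pair of control libraries they were found in 1929 to 2089 peaks, and per pair between groups in 2187 to 2628. How the peak boundaries were set is not given in the sources used here. Widths and covered bases may therefore not be independent between libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.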

Results

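The m6A peaks of mRNA were mapped in abdominal aortas of ApoE-/- mice with an aneurysm induced by angiotensin II (AAA, n = 3 libraries) and of control mice (n = 3 libraries). The comparison asks which transcripts carry m6A peaks in the aneurysmal aorta and which in the control aorta. The AAA lists held 11489, 12388 and 11822 peaks and the control lists 4842, 4208 and 4128. The labels list separate samples and do not say that each came from a different animal, so p-values measure the spread between these samples. Peak lists show where immunoprecipitated RNA was enriched enough to be called, so an absent peak is a peak not called at an unknown depth.

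More genes carried an m6A peak in AAA than in control libraries, 6495 ± 155 against 2893 ± 228 (SD, n = 3 each), a ratio of 2.25. The lists held 11900 ± 455 peaks per AAA library and 4393 ± 391 per control library, a ratio of 2.71. Peaks covered 10.5 ± 0.39 Mb of the genome in AAA and 3.27 ± 0.39 Mb in control libraries, and the median peak was 593 ± 12.8 bases wide against 431 ± 44.0 bases. Peaks also lay more often at the 3' end of genes in AAA libraries: the last 10% of the gene body held 30.5% ± 0.482 of AAA peaks and 25.3% ± 1.30 of control peaks. The first 10% held 10.90% ± 0.181 and 10.99% ± 0.235 (exact two-sided permutation p = 0.5). The libraries of the groups did not overlap in peaks, genes, width, covered length or share of the last 10%, each with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give. The highest running number in the peak names, which exceeds the number of listed peaks in every library, went the other way, 159004 ± 9286 in control against 69348 ± 7384 in AAA libraries (exact permutation p = 0.1). With each list cut to its top 4128 peaks by score, the ratio of genes became 1.07 and the ratio of median widths 2.16.

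**Figure D1:**
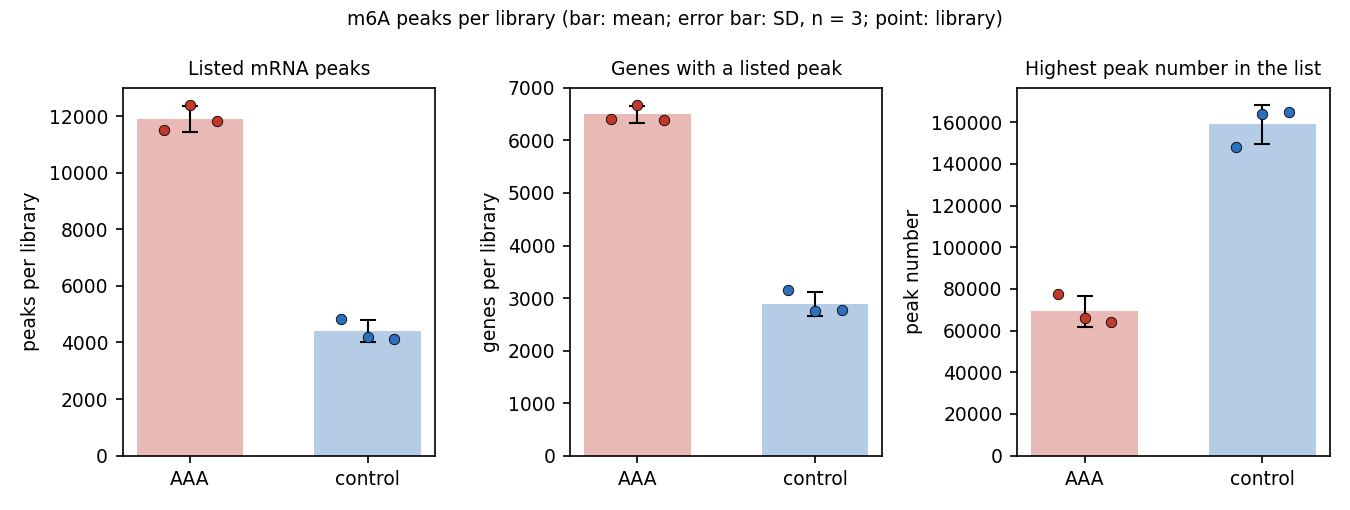
Listed mRNA peaks, genes with a listed peak and the highest peak number in the list, per library. Points are libraries, bars the group mean and error bars the SD (n = 3). AAA libraries held 11489 to 12388 peaks and control libraries 4128 to 4842, while the highest peak numbers were 64291 to 77821 in AAA and 148296 to 164840 in control libraries.

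The overlap of the lists in bases, measured by the Jaccard index, was higher within groups than between them. The Jaccard index in bases averaged 0.732 (0.714 to 0.752) over the 3 pairs of AAA libraries, 0.530 (0.522 to 0.536) over the 3 pairs of control libraries and 0.276 (0.245 to 0.324) over the 9 pairs between groups. The mean within groups exceeded the mean between groups by 0.355 (exact permutation p = 0.1 over 10 splits of the libraries, the smallest possible). The index between groups is limited by the unlike covered length, 10.5 Mb in AAA and 3.27 Mb in control libraries. Peaks of identical coordinates numbered 2187 to 2628 per pair of an AAA and a control library and 1929 to 2089 per pair of control libraries. By this count, control libraries shared no more peaks with each other than with the longer AAA lists. At equal list lengths the 3 means were 0.708, 0.537 and 0.410, and the excess was 0.213 (exact permutation p = 0.1). This cut made the number of peaks equal but not their widths, whose ratio of medians was then 2.16. The index counts bases, so the excess at equal list lengths cannot be separated from peak width.

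Merging the 6 lists gave 16148 regions in 8043 genes, of which 7922 are protein-coding. Of the regions, 3955 had a peak in all 3 AAA and no control library, 137 had one in all 3 control and no AAA library, and 2312 were found in all 6. Among genes, 2089 carried a peak in all 3 AAA and no control library, 85 the reverse, and 1740 were found in all 6. The control set was largely contained in the AAA set, with 92.7% of the 1878 genes found in all 3 control libraries also found in all 3 AAA libraries. In the other direction, 32.3% of the 5395 genes found in all 3 AAA libraries were found in all 3 control libraries. Most of this asymmetry went at equal list lengths, where 74.9% of 1796 and 57.8% of 2329 genes were shared in this way. Of the AAA-only regions that could be assigned to a gene, 2343 lay in genes with no control peak at all, and 1483 lay in 1069 genes whose control peaks were elsewhere in the gene. AAA regions with high scores were more often shared. Among regions whose lowest AAA score was 50 to 100, 2.30% were in all 3 control libraries, and among those with at least 3100, 74.6% were. The counts depended on list length: at equal lengths, 526 regions and 338 genes were AAA-only and 460 regions and 256 genes control-only. The better-scoring 50% of each list gave 2036 and 54 regions and 1386 and 35 genes. Control-only regions numbered 206 without control replicate 1 and 207 without control replicate 3.

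**Figure D2:**
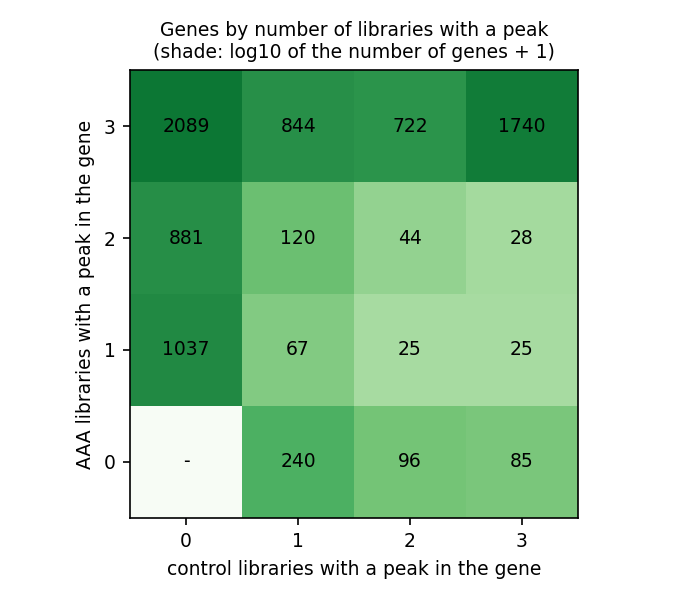
Genes by the number of AAA libraries (vertical axis) and control libraries (horizontal axis) in which they carry a peak. Each cell gives the number of genes and its shade the log10 of that number plus 1. The corners hold 2089 genes found in all 3 AAA libraries and no control, 85 genes in the opposite corner and 1740 genes found in all 6 libraries.

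The transcripts of the m6A machinery carried peaks themselves. Of 27 genes of writers, erasers and readers, 16 had a peak, 15.3 ± 0.577 per AAA and 10 ± 2 per control library (exact permutation p = 0.1). Wtap, a subunit of the methyltransferase complex, had its peaks in all 3 AAA and no control library (leading region chromosome 17, 12974068 to 12975474). Rbmx, a nuclear reader (chromosome X, 57386075 to 57388143), and Igf2bp2, a reader that stabilises mRNA (chromosome 16, 22059009 to 22060324), showed the same pattern. Virma, Zc3h13, Rbm15b and Cbll1 of the writer complex, the eraser Fto, the readers Ythdf2 and Ythdc1 and the translation factor Eif3a carried a peak in all 6 libraries. Rbm15 and Ythdf1 carried one in 3 AAA and 1 control library, Ythdf3 and Fmr1 in 3 AAA and 2 control libraries, and Ythdc2 in 1 AAA library. At equal list lengths, none of Wtap, Rbmx and Igf2bp2 kept 3 AAA libraries against 0, while Ythdf1 came to show that pattern. Fto then kept its peak in the 3 control libraries and in no AAA library. Fmr1 then had a peak in 2 more control than AAA libraries. These 2 changes came from the cut, which drops most of each AAA list and little of a control list. In the full lists, the mean best score of Fto was 678 in AAA and 297 in control libraries. For Fmr1 the means were 196 and 74.3, the latter over 2 control libraries. The scale of the score is not stated, and no difference in score was tested.

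Genes of the extracellular matrix and its turnover had more peaks in AAA libraries. Collagens and matrix proteins had a peak in 27.3 ± 4.73 genes per AAA and 10.3 ± 2.52 per control library, out of 48. In all 3 AAA and no control library were 7 of them, led by Loxl1, a lysyl oxidase that crosslinks elastin, Col1a2, the type I collagen alpha chain, Fbln2 and Tnxb. The Loxl1 peak spanned 1527 bases in each library (chromosome 9, 58311686 to 58313212), and that of Col1a2 spanned 1028 bases (chromosome 6, 4540516 to 4541543). Of 40 matrix proteases and inhibitors, 15 ± 2.65 had a peak per AAA library and 3.67 ± 1.53 per control library, and 8 were AAA-only. Mmp14, a membrane-bound collagenase, carried the same 918-base peak in all 3 AAA libraries (chromosome 14, 54440341 to 54441258) and none in controls. Over all peaks, 5900 to 6364 per pair of AAA libraries had identical coordinates. Equal lengths therefore do not single out these or other genes. Adamts1, a versican-cleaving protease, had 1916 ± 310 bases of peaks per AAA library (n = 3; chromosome 16, leading region 85793827 to 85796100). Adamts12 and Adam17, the sheddase of TNF, followed. At equal list lengths, Col1a2, Fbln2, Adamts12 and Adam17 no longer had 3 AAA libraries against 0. Each count per library differed with an exact permutation p = 0.1.

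**Figure D3:**
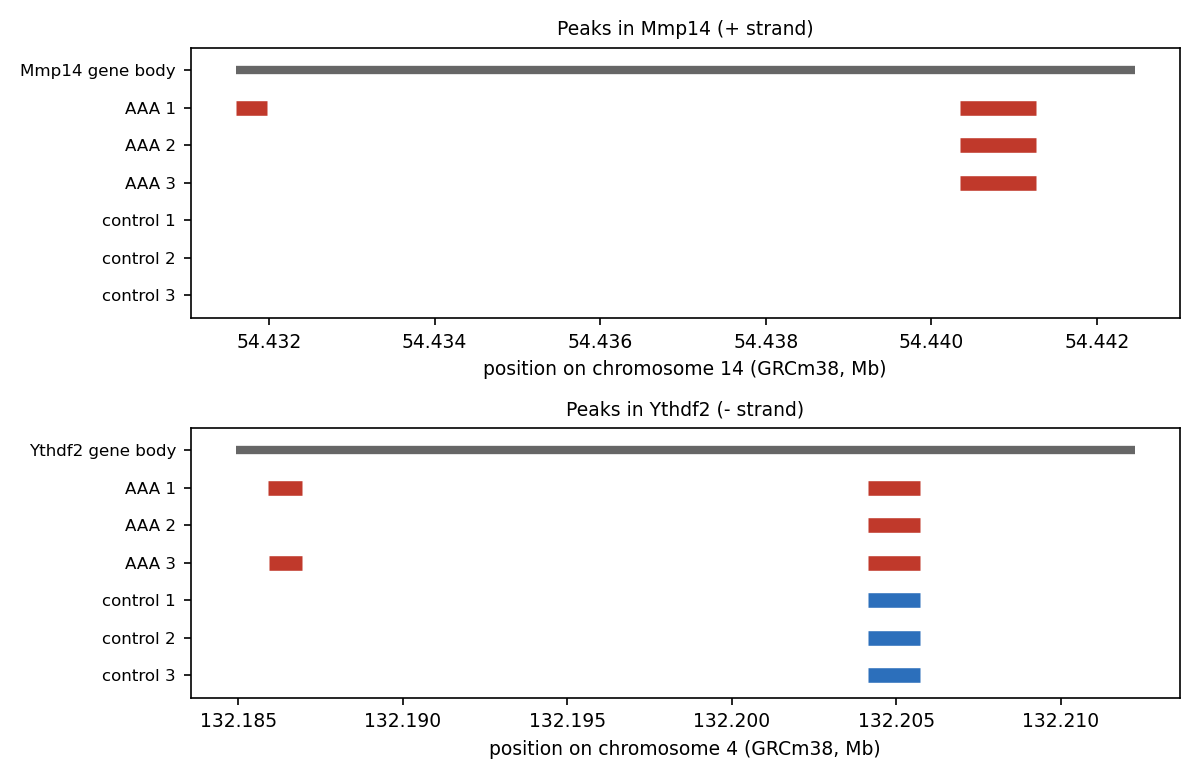
Peaks of the 6 libraries along the bodies of Mmp14 (chromosome 14) and Ythdf2 (chromosome 4), with position in Mb of GRCm38 on the horizontal axis and a row per library. Grey bars are gene bodies, red bars AAA peaks and blue bars control peaks. The Mmp14 peak at 54440341 to 54441258 is in the 3 AAA libraries, and the Ythdf2 peak at 132204132 to 132205715 is in all 6.

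Signalling genes behaved alike in number. For TGF-beta and BMP signalling, which governs matrix production and smooth muscle phenotype in the aorta, 26 ± 1 of 35 genes had a peak per AAA and 10.3 ± 2.31 per control library, and 10 genes were AAA-only. They included the ligands Tgfb3 (chromosome 12, 86077581 to 86079041, 1461 bases in each library) and Tgfb1, the receptor Bmpr2 (chromosome 1, 59867336 to 59868615) and Ski, a repressor of SMAD signalling. Of 36 Notch and Wnt genes, 25 ± 1.73 against 6.67 ± 0.577 had a peak, and 11 were AAA-only, among them the receptor Notch2 (chromosome 3, 98146053 to 98150367, a 4315-base peak in each AAA library), its target Hey2, the scaffold Axin1 and the coreceptor Lrp5. Of 26 genes of the renin-angiotensin and vasoactive list, 12.3 ± 2.31 against 2.33 ± 0.577 had a peak. The 6 AAA-only members included Agtr1a, the type 1 receptor of the angiotensin II used to induce the aneurysm (chromosome 13, 30380902 to 30382831), the endothelin receptors Ednra and Ednrb, and Prkg1, the cGMP-dependent kinase. Tgfb1, Agtr1a, Ednra, Ednrb and Prkg1 did not keep 3 AAA libraries against 0 at equal list lengths. The libraries of the groups did not overlap for any of these 3 lists (exact permutation p = 0.1 each).

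Peaks in immune genes were also more frequent in AAA libraries, with 1 library standing apart. Of 53 cytokines, chemokines and innate receptors, 18 ± 2 had a peak per AAA and 4.33 ± 2.52 per control library (exact permutation p = 0.1), and 7 were AAA-only, with Tnfrsf1b, a TNF receptor, Vcam1, an endothelial adhesion molecule, Tlr7 and Irf8 leading. Macrophage and monocyte markers had peaks in 23 genes in AAA replicate 1, in 12 each in AAA replicates 2 and 3, and in 5, 6 and 3 in the control libraries, out of 34. The 4 AAA-only markers were Abca1, a cholesterol exporter (chromosome 4, 53030787 to 53034083), the transcription factor Spi1, the receptor Clec7a and the scavenger receptor Msr1. T, B and NK cell markers had a peak in 9 ± 1 against 2.33 ± 0.577 genes of 28 (exact permutation p = 0.1), and the AAA-only members included Il7r, Cd22, Cd79b and Cd2. Neutrophil and mast cell markers had a peak in 1.67 ± 0.577 against 0.667 ± 0.577 genes of 18 (exact permutation p = 0.3), with S100a9 AAA-only. None of Tnfrsf1b, Vcam1, Tlr7, Irf8, Clec7a, Msr1, Cd79b, Cd2 and S100a9 kept 3 AAA libraries against 0 at equal list lengths.

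Markers of the resident cells of the wall carried peaks in both groups. Contractile smooth muscle genes had a peak in 14 ± 1.73 per AAA and 7.67 ± 2.31 per control library, out of 28, and Myl9, the myosin regulatory light chain, and Ldb3 were AAA-only. Genes of synthetic, dedifferentiated smooth muscle had a peak in 10.7 ± 0.577 against 7.67 ± 0.577 of 18, with Pdgfra and Mgp, an inhibitor of calcification, AAA-only. Endothelial markers had a peak in 16.3 ± 0.577 against 6.33 ± 4.16 of 25, the control libraries holding 5, 3 and 11. The AAA-only endothelial genes were S1pr1, the sphingosine-1-phosphate receptor (chromosome 3, 115710433 to 115713114), the VEGF receptor Kdr, Sox18 and Sox17. Fibroblast and adventitial markers had a peak in 6 ± 1.73 against 1.33 ± 0.577 of 21, with Pdgfra, which is in both lists, the AAA-only member. Markers of tissue around the aorta did likewise. Adipocyte and perivascular fat genes had a peak in 11.3 ± 2.31 against 4.33 ± 2.08 of 29, with Plin4, Ucp1 and Pparg AAA-only, and neural and Schwann cell genes in 8 ± 1 against 3 ± 1 of 15, with Dbh, the noradrenaline-forming enzyme, among the AAA-only genes. Skeletal muscle genes had a peak in 9.33 ± 0.577 against 6.33 ± 0.577 of 18, with Tnni2 AAA-only. Each of these counts differed with an exact permutation p = 0.1. No erythroid or platelet marker of 11 had a peak in any library. At equal list lengths, Ldb3, Mgp, Sox18, Sox17, Plin4, Ucp1, Pparg and Tnni2 no longer had 3 AAA libraries against 0.

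Lipid and housekeeping genes differed in how often they carried a peak. Of 28 lipoprotein and cholesterol genes, 9.67 ± 1.15 had a peak per AAA and 0.667 ± 1.15 per control library, and the 6 AAA-only members included Abca1, Lrp5 and Msr1. The list had 11, 9 and 9 genes with a peak in AAA replicates 1, 2 and 3 and 0, 0 and 2 in control replicates 1, 2 and 3, so without control replicate 3 no control library had any. Transcripts typical of liver also differed between libraries. Of 85 such genes in the reference, on a list drawn up after the values of some of them were seen, 30, 28 and 8 had a peak in AAA replicates 1, 2 and 3 and 4 in each control library (exact permutation p = 0.1). In 29 genes more AAA than control libraries had a peak, in 3 (Afp, Mug1 and Cyp3a11) more control libraries, and in 2 (Ambp and F5) as many. Alb, Apob, Ahsg, Apoa2 and Apoa5 were among 17 with a peak in AAA replicates 1 and 2 and in no other library, and 7 were AAA-only. Peak lists do not show from which tissue or cell a transcript came, and RNA levels were not analysed here. A difference in the tissue content of the samples therefore cannot be told apart from a difference in methylation, for these or other AAA-only genes. Apoptosis genes had a peak in 16 ± 1 against 6 ± 1.73 of 30, with Cflar, Bid, Fadd and Bbc3 leading 5 AAA-only members. Autophagy and lysosome genes had a peak in 12.7 ± 0.577 against 4.67 ± 0.577 of 32, with Mtor, Ambra1, Atg2a and Atg5 AAA-only. Cell cycle genes had few, 5.67 ± 1.15 against 1.67 ± 0.577 of 34, with Foxm1 and Top2a AAA-only. Chromatin regulators had the most in both groups, 44.3 ± 0.577 against 34 ± 2.65 of 53, and 5 were AAA-only, led by the H3K4 methyltransferase Kmt2b (chromosome 7, 30584994 to 30587029), the H3K27 demethylase Kdm6b, Kdm2a and Setd1a. Ribosomal proteins had a peak in 12.7 ± 1.15 against 5 ± 1.73 of 75, with Rpl19 and Rpl8 among the AAA-only genes, and oxidative phosphorylation genes in 5.67 ± 1.15 against 0.667 ± 0.577 of 63, with Ndufa12, Ndufs5 and Ndufa10 AAA-only. All 7 differences had an exact permutation p = 0.1. Of the genes named here, Msr1, Bid, Fadd, Bbc3, the 4 autophagy genes, Foxm1, Top2a, Kdm2a, Setd1a, Rpl8 and the 3 oxidative phosphorylation genes did not keep 3 AAA libraries against 0 at equal list lengths.

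At the criterion of 3 libraries against 0, no list stood out from the general excess of AAA-only genes. AAA libraries held more list genes with a peak in 24 of 25 lists, and in 23 of them the groups did not overlap, where chance gives 5% in one given direction for a single list. The lists are read from the same 6 libraries, whose totals of genes with a peak do not overlap either, so these counts are not independent of that difference or of each other. No list gene was found in all 3 control and no AAA library. Of 46 Fisher exact tests on 23 lists, 0 passed an adjusted p of 0.05 (Benjamini-Hochberg, smallest adjusted p = 0.940) and 2 had an unadjusted p under 0.05. Of the chromatin regulators with a peak, 5 of 45 were AAA-only (11.1%, against 26.1% of other genes, Fisher exact p = 0.0251), and of the lipoprotein and cholesterol genes, 6 of 11 were (54.5% against 25.9%, Fisher exact p = 0.0409). With the looser criterion of at least 2 more AAA than control libraries, 1 test passed, with 10 of 45 chromatin regulators (22.2%) below the 47.6% of other genes (Fisher exact adjusted p = 0.0362). At equal list lengths, 2 of 41 chromatin regulators were AAA-only (4.88% against 7.07% of other genes, Fisher exact p = 1), and the smallest p was that of Notch and Wnt signalling, with 6 of 21 (28.6% against 6.96%, Fisher exact adjusted p = 0.098). Over the alternatives, the smallest adjusted p ranged from 0.0362 to 1. Of the 79 named AAA-only genes, 34 were still AAA-only at equal list lengths and 21 had no peak left.

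**Figure D4:**
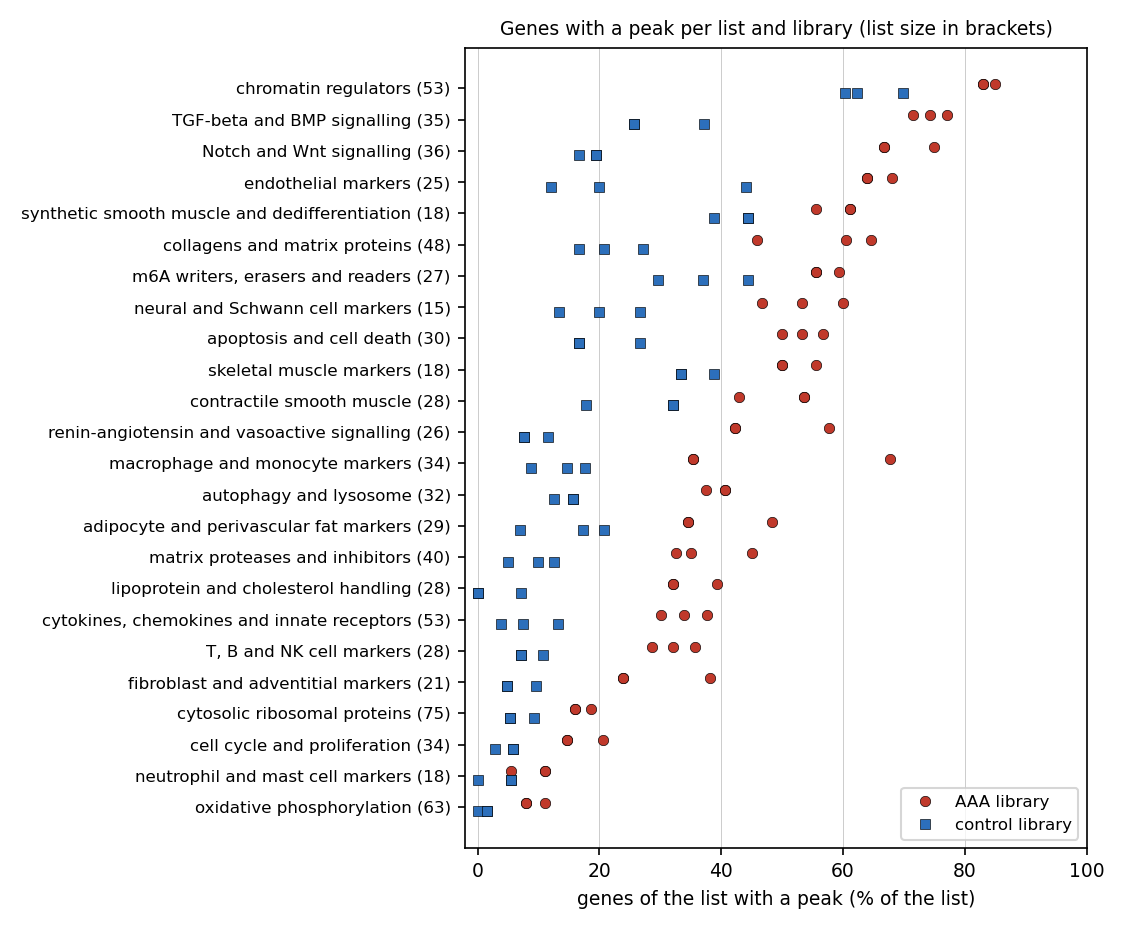
Share of the genes of each list that carry a peak (horizontal axis, % of the list), for AAA libraries (circles) and control libraries (squares), 1 symbol per library. The list size is in brackets and the list without any peak is left out. The groups do not overlap in 23 lists, and AAA replicate 1 lies apart in macrophage and monocyte markers, with 23 genes against 12 and 12.

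Outside the lists, the leading AAA-only genes by score were Chga, which encodes the neuroendocrine granule protein chromogranin A (chromosome 12, 102562598 to 102563073), the unconventional myosin Myo9b, the prolyl hydroxylase P3h3 and Zbtb22. Adnp, the transcription factor Cebpa and Cenpb, which binds centromeric DNA, followed. Of the 8 leading control-only genes, 4930467E23Rik, Gm15319 and Gm20778 lie on chromosome 8 (leading regions 19729576 to 19730002, 20337664 to 20339033 and 20061801 to 20063170), Saxo1 and Zfp980 on chromosome 4, Gm3629 and the axonemal dynein Dnah12 on chromosome 14, and Gm6367 on chromosome 5. Of all 85 control-only genes, 13 belonged to the olfactory receptor, vomeronasal receptor and Pramel families, a grouping chosen after the values were seen. Among the genes found in all 6 libraries, the highest mean scores were those of the non-muscle myosin Myh10, the Golgi protein Golim4, the cohesin subunit Smc1a, the kinase Cdk11b and the splicing helicase Ddx46. The Smc1a region (chromosome X, 152027694 to 152027952) and the Ddx46 region (chromosome 13, 55645371 to 55645467) had a peak in all 6 libraries. So had the leading regions of Myh10 and Golim4. The leading region of Cdk11b (chromosome 4, 155640747 to 155640812) had a peak in 2 AAA libraries and no control library. The sequences of these regions were not examined, so whether they hold an m6A motif is unknown.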

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

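Over 97 values of the main results recomputed under alternatives, 84 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 12 counts moved further, 1 list passed the threshold and 0 reversed. Single named genes are not among these values; of them, Fmr1 changed sign at equal list lengths, from 1 to -2 (AAA minus control libraries), and Fto went from 0 to -3. AAA-only regions (3955) became 2036 in the better-scoring 50% of each list and 526 at equal list lengths, control-only regions (137) 54 and 460, AAA-only genes (2089) 1386 and 338, and control-only genes (85) 35 and 256. The upper parts of lists of different length are cut at different depths, so these counts change by construction. The looser criterion gave 3814 AAA-only and 206 control-only genes and 1 list past the threshold, chromatin regulators; it admits more genes by construction. Leaving out 1 library gave 141 to 207 control-only regions (206 without control replicate 1 and 207 without control replicate 3), 4271 to 5051 AAA-only regions, 2293 to 2507 AAA-only genes and 88 to 122 control-only genes, since a region or gene then needs fewer libraries; no list passed. The tests on values per library cannot reach 0.05 in any setting, so they show direction only. The ratio of genes with a peak moved from 2.25 to 1.07 at equal list lengths. Unambiguous peaks only, chosen after seeing the data, left 2080 and 86 genes. Of the 79 named AAA-only genes, 45 were AAA-only in the better-scoring 50% and 34 at equal lengths.

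With the replicate block, the ratios were 2.71 for peaks, 1.38 for width and 2.25 for genes, each with a sign-flip p of 0.25, the smallest possible, and no call changed. The labels only share replicate numbers and state no pairing. Deviations of same-numbered libraries from their group means had correlations of -0.0041, 0.0052 and 0.0033. Over all 9 pairs of an AAA and a control library, the largest was 0.00924 in size. This gave no sign of a pairing, but it cannot exclude that same-numbered samples were handled together. The search for the motif, with its window of bases, and the assignment by exons were not run. The unknown read depth limits all counts of absent peaks.

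AAA-only and control-only regions together numbered 4092 and the highest of the other splits of the libraries gave 65; for genes the values were 2174 and 33, and for lists past the threshold 0 and 0. As many were found in 1, 1 and 10 of 10 splits, which are too few for a share under 0.05.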

Other observations

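Apart from the comparison of peaks per library, which was planned, and the second list of macrophage genes, fixed before its values were seen, all tests in this part were chosen after the results had been seen. Genes are not independent replicates, so the Fisher tests describe these libraries. Genes with peaks in all 6 libraries were rich in chromatin regulators. Of the 45 with a peak, 29 had one in all 6 libraries (64.4%, against 21.4% of other genes; Fisher exact adjusted p = 1.61e-08), and no other list passed. The list also stood out in how many of its protein-coding members had a peak in any library, 84.9% against 36.1% of other protein-coding genes (Fisher exact adjusted p = 8.71e-12), and it led 11 of 25 lists above the other protein-coding genes, followed by Notch and Wnt signalling with 80.6% (adjusted p = 7.99e-07) and TGF-beta and BMP signalling with 80% (adjusted p = 1.19e-06). Below the other genes were 3 lists. A peak was found in 21.3% of ribosomal protein genes (Fisher exact adjusted p = 0.024) and in 14.3% of oxidative phosphorylation genes (adjusted p = 0.000908), and in 0 of 11 erythroid and platelet markers (adjusted p = 0.0272). RNA levels were not analysed here, so expression and methylation cannot be separated in these shares. Gene length was not taken into account either, although peaks were assigned over whole gene bodies. Genes found in all 6 libraries were longer than AAA-only genes, with a median of 42 kb against 28.9 kb. The lengths of the list genes were not compared, so a part of length in these shares cannot be excluded.

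The control libraries had fewer mRNA peaks but peak numbers up to 164840, of which at most 2.78% ± 0.422 were listed, against at most 17.3% ± 2.22 in AAA libraries (n = 3 each; exact permutation p = 0.1). The share of AAA regions found in all 3 control libraries was 72.2 percentage points higher in the highest than in the lowest score class. Shorter control lists would give this, but so could fewer methylated mRNAs in control aortas. The difference therefore does not decide whether list length made the imbalance of AAA-only over control-only regions. A shorter list alone adds no peaks, and the 137 control-only regions exceeded by 81 the 56 of the most frequent of 18 arrangements of 3 libraries that mix the groups. A candidate explanation for the shorter control lists is that more of their calls were spread over the genome than over genes. Across the 19 autosomes, calls per Mb, counted from the peak numbers, went with the density of protein-coding genes in AAA libraries (Pearson r 0.689, 0.675 and 0.674, Spearman rho 0.802, 0.804 and 0.788, permutation adjusted p at most 0.00282 over 6 libraries) while control libraries had r of -0.266, -0.41 and -0.319 and rho of -0.188, -0.319 and -0.216 (adjusted p at least 0.122; AAA against control r, exact permutation p = 0.1). The r without the 2 chromosomes farthest from the median gene density was 0.695 to 0.774 and -0.59 to -0.385. Calls spread over the genome and fewer methylated mRNAs in control aortas would both give fewer listed mRNA peaks in control libraries. The peak counts (exact permutation p = 0.1) therefore cannot tell these explanations apart.

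Control-only genes included members of gene families known from sensory organs and the germline. Olfactory receptor, vomeronasal receptor and Pramel genes made up 13 of 85 control-only genes (15.3%, against 0.858% of all genes with a peak), and 30, 39 and 36 of them had a peak in control libraries against 6, 5 and 3 in AAA libraries, a gap of at least 24 between any control and any AAA library. Reads that do not come from aortic mRNA may give such peaks. Reads shared between near-identical copies may do so too: 59.3% of the control-only genes with a family name lay within 500 kb of a gene of the same name stem, against 9.7% of the genes in all 6 libraries (Fisher exact p = 3.43e-18). Both explanations predict peaks in the same clustered families, so they cannot be told apart here, and the families were picked from the control-only genes themselves.

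AAA replicate 1 carried peaks in 10 macrophage and monocyte markers that no other AAA library had, C1qa, C1qb, C1qc, Cybb, Gpnmb, Fcgr3, Fcer1g, Cd14, Itgax and Ptprc, and no control library had them. More macrophage RNA in this library may account for them: a second list of 60 macrophage genes that are in no other list had a peak in 33, 22 and 27 genes in AAA replicates 1, 2 and 3, and held 8 of the 404 genes with a peak in AAA replicate 1 alone of the AAA libraries against 1 of the 750 in 1 of the others (Fisher exact p = 0.00134), although the library itself was picked for its markers. A longer list of peaks is argued against, since AAA replicate 1 differed by -333 peaks from the shorter of the other lists. In genes with a peak it lay between them, with 6413 against 6674 in AAA replicate 2 and 6398 in AAA replicate 3. Its highest peak number was above theirs (77821, against 65932 and 64291), so the argument covers the listed peaks only. Of the 34 markers, 6 are also in another list, none of the 10 is, and 11, the abundant Lyz2 and Cd68 among them, had no peak in any library. Methylation gained on these transcripts without more of them stays open, as RNA levels were not analysed here.

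AAA-only genes were shorter than genes found in all 6 libraries, with a median length of 28.9 kb against 42 kb (permutation p = 1e-05, the smallest that the permutations can give), and lay among more protein-coding genes within 500 kb, 14 against 12 (permutation p = 9e-05). The same was compared among genes with a best score at the cap in all 3 AAA libraries (45 AAA-only and 751 in all 6). Their lengths were 20.2 and 45.6 kb (permutation p = 0.0238). The difference in gene density, 15 against 11, missed 0.05 (permutation p = 0.0943). A gene was AAA-only when no control peak lay anywhere in its body, and a longer body leaves more room for a control peak. The length tests therefore cannot separate gene length from the definition of the groups. Genes are not independent replicates, so the permutation p-values describe these libraries only.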
